A study of Mus musculus with 8 samples.

How the data were processed

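RNA immunoprecipitation sequencing (RIP-seq) was applied to dissociated cells of the mouse cortex at embryonic day 12.5. In this assay an antibody against a protein is used to pull that protein down from a cell lysate, and the RNA that comes with it is sequenced. One group of 4 libraries came from pull-downs with an antibody against Exosc10, an exoribonuclease of the nuclear RNA exosome. The other group of 4 came from mock pull-downs with normal rabbit IgG, which measure RNA captured without the specific antibody. Groups and replicate numbers were taken from the sample titles. No library of input RNA was analysed here, so every value compares one pull-down with the other and none gives enrichment over the RNA content of the cells.

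The authors deposited one file per library, which holds a read count for each of 54838 mouse Ensembl gene IDs, with no normalization. The order of the IDs was checked and was identical in all files. Per the submitters' processing notes, the tools named were bcl2fastq 2.17.1.14, STAR 2.5.2a and featureCounts 1.5.0-p1, and the genome build was mm10. The annotation release, the strand setting and the treatment of reads that map to several genes were not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies could therefore be divided between IDs in a way that cannot be checked from the counts. The sources also name no removal of duplicate reads and no molecular identifiers, so a count is not necessarily an independent RNA molecule.

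The files pair the IDs with no gene symbols. The RefSeq table used for names, of assembly GRCm38.p6, held 49997 genes and no Ensembl IDs, and 0 of the 54838 IDs were matched. The 22 gene lists by symbol that had been fixed before the data were examined could therefore not be tested, and the genes fixed for naming by symbol, Exosc10, Aen and Bbc3, are not reported. Shares of counts in mitochondrially encoded genes and in small noncoding RNAs were not computed for the same reason. Genes are given by their Ensembl ID, and only 2 IDs are printed per direction. They are those with the largest absolute log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM (the count scaled to a common library total) and no overlap between the 4 values of one group and the 4 of the other. This is the naming rule fixed at the same time as the lists, without its part on symbols and shortened to 2 per direction; 1130 genes in the higher and 646 in the lower direction met it.

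Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16716 genes whose share of a library's counts was lowest at 99.87%. Libraries were scaled by the trimmed mean of M-values (TMM), and a quasi-likelihood F-test compared the groups with no covariate. P-values were adjusted by the Benjamini-Hochberg method and read at 0.05. Fold changes are given as Exosc10 over IgG on the log2 scale. The standard error (SE) of a fold change is its size divided by the square root of the F statistic, and intervals are 95% confidence intervals from the same fit. CPM values are scaled by TMM. Log2 CPM values used a prior count of 2. The labels do not say whether the libraries of a group came from separate litters or cultures, so the p-values measure the spread between these libraries, which may be technical.

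Library totals, the number of genes detected after all libraries were thinned at random to the smallest total of 20967743 counts, and the share of counts in the 10 highest genes were compared by an exact two-sided permutation test over the 70 assignments of 8 libraries to the groups, whose smallest p is 0.0286. These 3 measures were adjusted as one family. Markers of the G1, S and G2M phases of the cell cycle, which scran 1.30.0 ships as ordered pairs of mouse Ensembl IDs, were added after the data had been seen. Each gene was given to the phase in which it stands first in a pair most often, net of standing second. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry.

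The gene test was checked on counts simulated for the 16716 genes at the real means, dispersions and library sizes, with 200 genes changed. It recovered 2.0% of 50 genes changed 1.5-fold, 44.0% of 50 changed 2-fold, 80.0% of 50 changed 3-fold and 92.0% of 50 changed 4-fold. Of its 114 calls, 5 were of unchanged genes. The data gave more calls, 2297, and the adjusted threshold depends on that number. These shares are therefore not the power of the test on the data. The alternatives were DESeq2 1.42.0, limma-voom with sample weights, scaling by library totals, by median ratios or by the upper quartile, no filter, a filter at a mean of 5 CPM, the replicate number as a block, thinning to equal depth, and leaving out each library in turn. Leaving out both libraries numbered 1 and leaving out the 50 most abundant genes were added after the data had been seen. The correction for gene length and the exclusion of gene classes could not be run without names or lengths for the IDs.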

Results

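The binding of RNA by Exosc10 in the developing mouse cortex was profiled by RIP-seq at embryonic day 12.5. Pull-downs with an Exosc10 antibody (n = 4) were set against mock pull-downs with normal rabbit IgG (n = 4). Total gene counts ranged from 21731971 to 34506709 in the Exosc10 libraries and from 20967743 to 30199449 in the IgG libraries. The mean totals were 29417900 ± 5500600 (SD, n = 4) and 25640600 ± 3775390 (SD, n = 4), a difference within the spread between libraries (exact two-sided permutation test, p = 0.286, adjusted p = 0.286). At least 1 read was counted for 30694 of the 54838 genes over all libraries, and 16716 genes had enough counts to be tested. Within the Exosc10 group, Spearman correlations of log2 CPM across genes ranged from 0.965 to 0.993 over the 6 pairs of libraries. They ranged from 0.963 to 0.988 within the IgG group and from 0.938 to 0.976 between the groups. No pair of libraries agreed within sampling noise, the lowest chi-square statistic per gene being 19.6, so none was treated as a repeat deposit of another; this does not show that they came from separate cultures or animals.

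The first principal component of log2 CPM held 34.4% of the variance and separated the 4 Exosc10 libraries, at 19.7 to 55.0, from the 4 IgG libraries, at -58.3 to 11.5. The second component held 22.1%. On it the libraries numbered 1 lay apart from the other libraries of their own group, at 30.3 for Exosc10 library 1 against -39.0 to -24.0 for the others, and at 54.8 for IgG library 1 against -9.8 to 19.0 for the others.

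**Figure D1:**
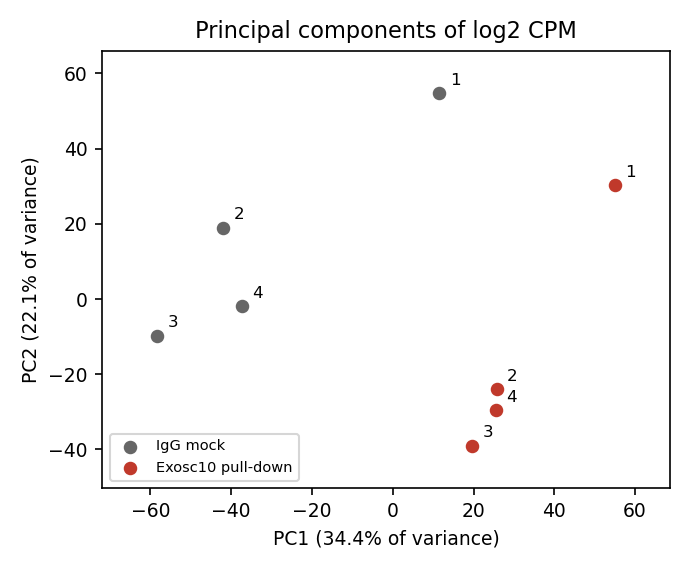
The first against the second principal component of log2 CPM over the 16716 tested genes, one point per library, numbered by replicate, with the share of variance on each axis. Exosc10 libraries lie to the right of the IgG libraries, and both libraries numbered 1 lie above the others of their group.

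The question put to the data was which transcripts took a larger share of the Exosc10 pull-down than of the mock pull-down. Scaling makes each value a share of its pull-down, so a higher or lower gene is not shown to be recovered in a larger or smaller amount. Of the 16716 genes tested, 1324 (7.92%) were higher and 973 (5.82%) were lower in the Exosc10 pull-down, 2297 in all, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Among the called genes most differences were moderate. They passed a threshold on the same data that small differences seldom pass, so their sizes are not those of all differences. The median log2 fold change was 0.84 among the higher genes, a 1.79-fold difference, with the middle of the distribution between 0.70 and 1.04, and it was -0.85 among the lower genes, with the middle between -1.04 and -0.71. The median SE of a called gene was 0.20 on the log2 scale. At least a 2-fold difference was reached by 380 higher and 282 lower genes, 662 in all, and at least a 4-fold difference by 7 higher and 29 lower genes. The called fold changes ran from -4.51 to 3.05. No gene was counted with at least 10 reads in each Exosc10 library and at 0 in all IgG libraries, and none the other way round. No gene was thus present in 1 pull-down alone by this rule, and weaker differences in presence were not examined.

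In 1169 of the 1324 higher genes the lowest Exosc10 value lay above the highest IgG value, and in 774 of the 973 lower genes the highest Exosc10 value lay below the lowest IgG value. These genes had been chosen by the test on the same values, so their separation is no independent support. Over all tested genes, called ones included, the 2 groups did not overlap in 19.1%, against 2.86% expected by chance for a single gene. Genes share deviations between libraries, so the share in a single grouping can lie far from that by chance. It was not computed for other splits, and chance is not excluded.

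The higher gene with the largest fold change under the naming rule was ENSMUSG00000058569, at 817 ± 187 CPM in the Exosc10 libraries and 174 ± 24.1 CPM in the IgG libraries (SD, n = 4 each). Its log2 fold change was 2.23 ± 0.21 (SE), with a 95% confidence interval of 1.78 to 2.68 and an adjusted p of 0.000195 in edgeR's quasi-likelihood test. ENSMUSG00000021025 followed, at 80.3 ± 8.3 CPM with Exosc10 and 21.4 ± 3.9 CPM with IgG (SD, n = 4 each), a log2 fold change of 1.90 ± 0.18 (SE, interval 1.51 to 2.30, edgeR adjusted p = 0.000195). Among the lower genes, ENSMUSG00000064368 stood at 442 ± 118 CPM with Exosc10 and 2676 ± 387 CPM with IgG (SD, n = 4 each), and its log2 fold change was -2.60 ± 0.23 (SE, interval -3.09 to -2.11, edgeR adjusted p = 0.000195). ENSMUSG00000064345 stood at 420 ± 225 CPM with Exosc10 and 2415 ± 903 CPM with IgG (SD, n = 4 each), with a log2 fold change of -2.52 ± 0.41 (SE, interval -3.41 to -1.64, edgeR adjusted p = 0.00262). The 2 lower genes ranked 19 and 22 by mean CPM among all tested genes, and the 2 higher genes ranked 190 and 5288. Each of the 4 genes rested on at least 492 reads in every library, and each kept its direction and its call in every alternative that tested it.

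**Figure D2:**
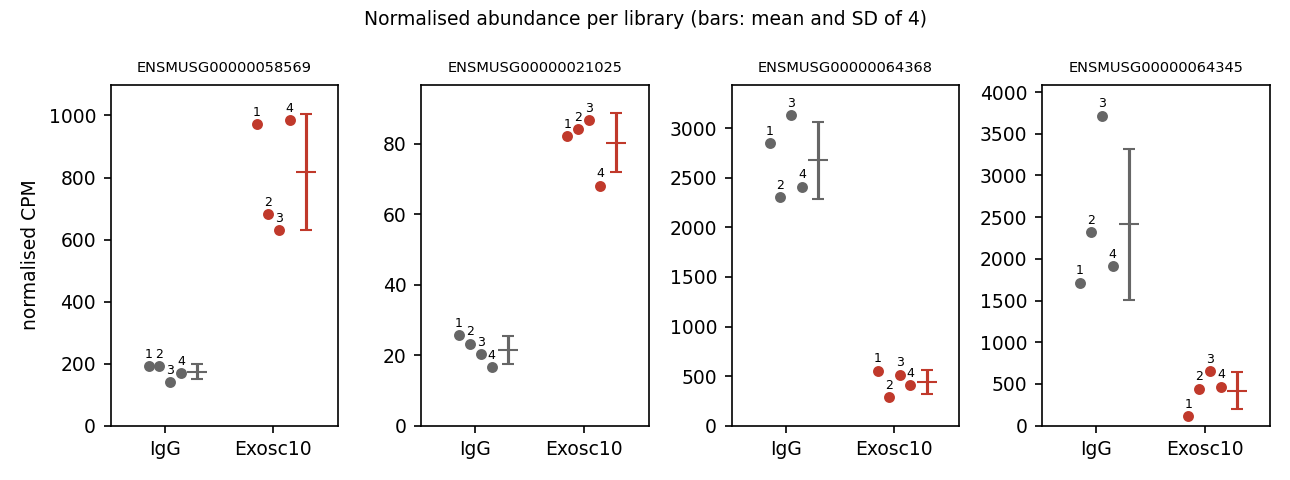
Normalised CPM of the 4 printed genes in each library, with points numbered by replicate and bars for the mean and SD of 4 libraries, on linear axes from 0. The Exosc10 and IgG points do not overlap in any of the 4 genes, with 631 to 985 CPM against 141 to 193 CPM for ENSMUSG00000058569 and 291 to 554 CPM against 2307 to 3136 CPM for ENSMUSG00000064368.

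Calls were spread unevenly over the range of abundance. Among the decile of tested genes with the highest mean CPM, 257 were higher and 112 lower in the Exosc10 pull-down, and among the decile below it 242 were higher and 98 lower. In the fourth decile, with a mean of 5.02 to 11.9 CPM, 77 were higher and 119 lower, and in the scarcest decile, at a mean of 0.251 to 0.821 CPM, 5 were higher and 18 lower. After TMM scaling, the median log2 fold change of all genes in a decile was -0.24 in the scarcest and -0.26 in the second, and 0.10 in the ninth and 0.08 in the most abundant, and the median SE of a single gene was 0.59 in the scarcest and 0.20 in the most abundant, so that fewer differences were detectable among scarce genes. At the very top of the range the balance was different. Of the 10 most abundant genes 3 were lower and 0 higher, of the top 50 genes 13 were lower and 7 higher, and of the top 500 genes 42 were lower and 78 higher.

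**Figure D3:**
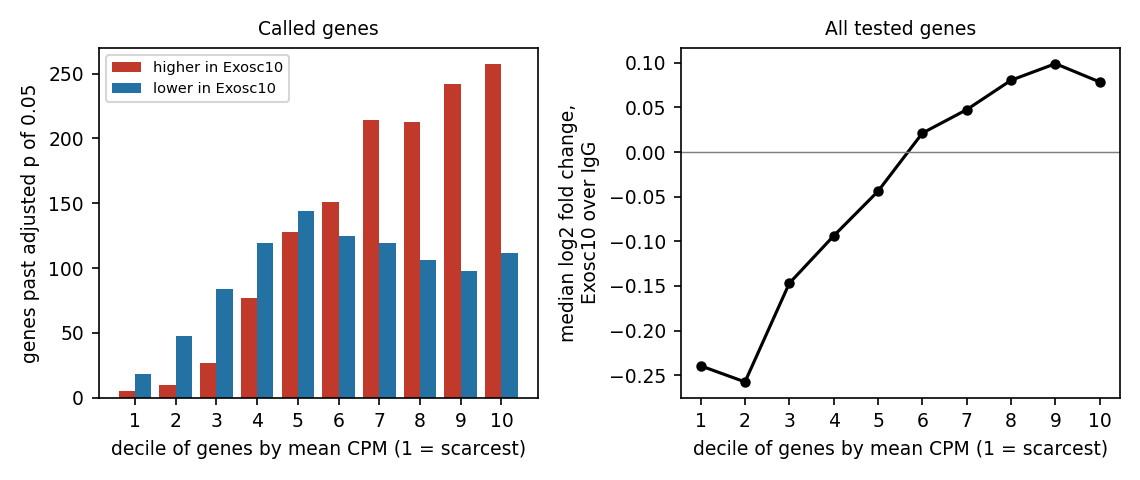
Left, the number of genes past the edgeR threshold in each direction by decile of mean CPM, from 1 for the scarcest to 10 for the most abundant. Right, the median log2 fold change, Exosc10 over IgG, of all tested genes in the same deciles, which runs from -0.26 in the second to 0.10 in the ninth.

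**Figure D4:**
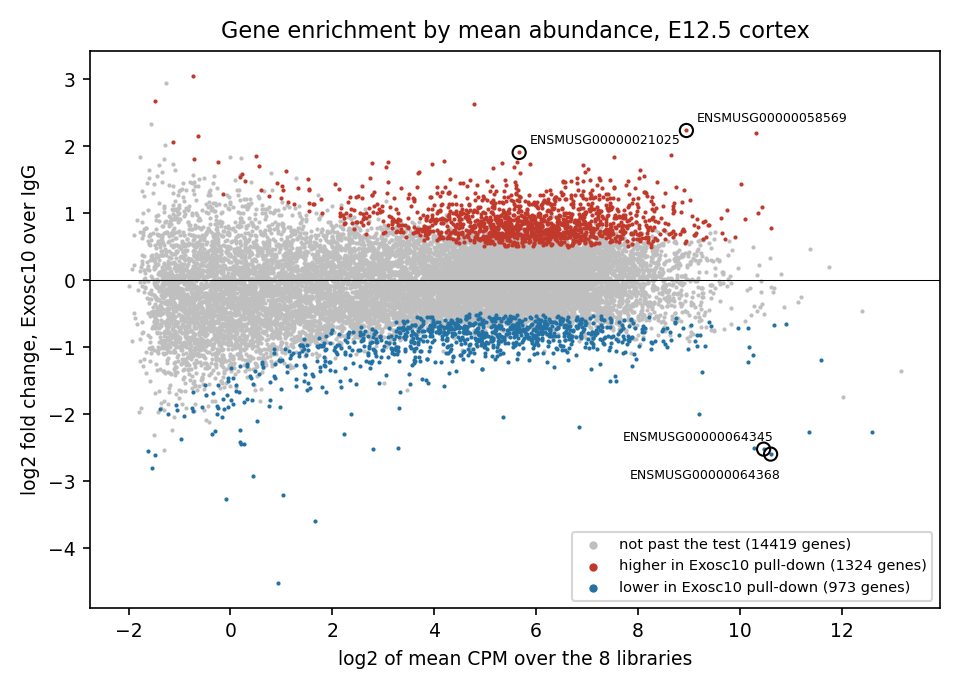
The log2 fold change, Exosc10 over IgG, against the log2 of the mean CPM for all 16716 tested genes, coloured by the edgeR call, with the 4 printed genes circled. The 1324 higher genes lie mostly at middle and high abundance, and a small set of very abundant genes lies more than 2 log2 units below 0.

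The concentration of the counts was compared as well. The 10 highest genes of a library took 3.14% ± 0.45 (SD, n = 4) of the counts in the Exosc10 group and 5.67% ± 1.75 (SD, n = 4) in the IgG group, where the highest Exosc10 library, at 3.73%, lay just below the lowest IgG library, at 3.85%. The exact permutation test gave p = 0.0286, the smallest it can give, and 0.0857 after adjustment over the 3 measures, which does not pass 0.05. With the 100 highest genes the exact permutation p was 0.0571, and the groups overlapped. The highest Exosc10 library, at 13.2%, lay above the lowest IgG library, at 13.1%. The exact permutation p was also 0.0571 without any one of the Exosc10 libraries, although the remaining values still did not overlap. Groups of unequal size have no mirrored assignment, so that p is not comparable with the one for 4 against 4. At equal depth, 22809 ± 399 genes (SD, n = 4) were detected in the Exosc10 and 22174 ± 339 (SD, n = 4) in the IgG libraries (exact permutation p = 0.0571, adjusted 0.0857). With at least 5 counts in place of 1 the order turned, to 17665 ± 151 and 18235 ± 240 genes (SD, n = 4 each; exact permutation p = 0.0286). The 1324 higher genes together took 17.4% ± 0.32 (SD, n = 4) of the counts in the Exosc10 libraries and 9.50% ± 1.29 (SD, n = 4) in the IgG libraries, and the 973 lower genes took 5.39% ± 0.22 and 11.2% ± 1.27 (SD, n = 4 each). These last shares describe genes that the test had chosen on the same libraries.

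The number of calls changed with the libraries left out, with the test and with the replicate number as a block. Leaving out a library also leaves fewer values to test, which can by itself lower the count. A lower count therefore does not mark the library as unusual. The number of calls was 6374 with limma-voom and sample weights. With edgeR it was 930 without Exosc10 library 2, 1370 without library 3 and 880 without library 4, and 4046 without IgG library 1, 1275 without library 2, 905 without library 3 and 1040 without library 4, against 2772 without Exosc10 library 1 and 5463 without both libraries numbered 1. With the replicate number as a block in edgeR, 4495 genes passed, 2489 higher and 2006 lower, and 752 of them were over 2-fold. The biological coefficient of variation was 0.199 with the block and 0.265 without it. The 2297 calls came from the fit without the block, so variation shared by libraries of the same number stayed in its error. The counts over 2-fold changed with the libraries left out and with the test too. Without IgG library 1 they were 649 higher and 545 lower genes, 1194 in all. They were 620 higher and 562 lower, 1182 in all, without both libraries numbered 1. With limma-voom they were 685 higher and 615 lower, 1300 in all. Without IgG library 3 the total was 428. The lower genes over 2-fold were 153 without Exosc10 library 2 and 155 without library 4, and 169 without IgG library 3 and 184 without library 4. Scaling by the upper quartile moved the median of all tested genes to -0.11 from -0.03 and turned the balance of calls, to 1025 higher and 1369 lower genes, so that 42.8% of calls were higher against 57.6% under TMM.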

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

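In 30 groups of 4 libraries, covering the library measures, the 4 printed genes and the cell cycle markers, no highest or lowest library lay far enough from the others to pass Dixon's test.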

How the results depend on the processing

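The alternatives tested 2105 to 2297 of the 2297 calls. Each call kept its sign wherever it was tested, and none was called in the opposite direction. The calls had been chosen on the same libraries, so their shared sign is no independent support. Counts stayed within 1.5 times with DESeq2 (1875 higher, 1421 lower), library totals (1113 and 997), median ratios (1340 and 971), the upper quartile (1025 and 1369), no filter (1697 and 1072), a mean of at least 5 CPM (1237 and 1162), thinning (1292 and 990) and without the 50 most abundant genes (1324 and 953). They moved further with limma-voom, to 6374 genes (3363 higher, 3011 lower), 1300 of them over 2-fold (685 and 615), and the cause was not tested. Leaving out 1 library gave 880 to 4046 genes, 588 to 2218 higher and 261 to 1828 lower, and over 2-fold 428 to 1194, of which 259 to 649 higher and 153 to 545 lower. Every range has its high end without IgG library 1. The low end came without Exosc10 library 4 for all calls and for lower genes, without Exosc10 library 2 for lower genes over 2-fold, and without IgG library 3 for the rest. Without both libraries numbered 1, 5463 genes passed (2908 higher, 2555 lower), 1182 over 2-fold (620 and 562), 2259 of them among the 2297, with a biological coefficient of variation of 0.186 against 0.265; the cause was not tested.

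Libraries of the same number deviated from their group means with correlations of 0.34, 0.095, 0.34 and 0.22 for numbers 1 to 4. One lay under 0.1, so numbers were not paired. Pairing stays open, as all 8 libraries correlated best with their own number. With the replicate block 4495 genes passed (2489 higher, 2006 lower), 2294 of the 2297 among them.

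Of the library measures, the difference in genes detected was 634.5 with at least 1 count and -570.5 with at least 5. The share in the highest genes kept its direction without each library in turn. Its exact permutation p was 0.0286, and 0.0571 with the 100 highest genes, where the groups overlapped. It was also 0.0571 without Exosc10 library 1, 2, 3 or 4. There the groups did not overlap, and their unequal sizes make the p not comparable. The median of the G1 markers was 0.15 with the 11 tested markers of a single phase, against -0.12 with all 240. That of the G2M markers ran from -0.012 without Exosc10 library 1 to 0.13 without IgG library 1, against 0.08. The 22 gene lists, the length correction, alone and with the block, and the exclusion of gene classes were not run. The test found 44.0% of 2-fold changes in a simulation that changed only 200 genes. With 2297 calls in the data the adjusted threshold differs, so this share is not the power of the real test. A gene without a call is not shown to be unbound.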

Other observations

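Cell cycle markers were examined because their Ensembl IDs could be matched without symbols. Of all tested genes, 7.92% were higher and 5.82% lower. In the eighth decile by mean CPM, at 54.7 to 83.3 CPM, 213 of 1671 genes were higher and 106 lower, with a median log2 fold change of 0.08. Of 210 tested S-phase markers, 21 were higher and 6 lower in the Exosc10 pull-down, also 21 and 6 when adjusted over the list alone. Their median log2 fold change was 0.08, and 0.03 to 0.17 over 14 alternatives. More higher than lower genes is thus not particular to these markers. Of 190 G2M markers, 18 were higher and 9 lower (18 and 10 adjusted over the list alone), with a median of 0.08 that became -0.01 without Exosc10 library 1. Of 240 G1 markers, 12 were higher and 17 lower (10 and 15 adjusted over the list alone), with a median of -0.12. With only markers of a single phase the median was 0.15, but that list held just 11 tested genes (camera adjusted p = 0.568). None of the 3 lists stood apart from the other genes in limma's camera, at an adjusted p of 0.168 each, or 0.600 each with an estimated correlation, and over 14 alternatives the lowest adjusted p was 0.0610. In limma's fry, which asks whether a list moves one way on balance, the adjusted p was 0.124 for S, 0.181 for G1 and 0.287 for G2M.

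For the patterns below, the tests of the splits for the gene counts, of a shared preparation, and of depth and of the libraries numbered 1 for the abundance trend were fixed only after results had been seen. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave 2297 genes, and the highest other gave 4. A share of 1 in 35 is the smallest these splits can give, so they do not exclude chance. Every other split mixes Exosc10 and IgG libraries, so a group difference widens its spread and lowers its calls. The same held for the 662 genes over 2-fold, with 1 split of 35 and again 4 as the highest other. When the 50 most abundant genes were left out, 99.2% of the 2277 calls outside them remained with their sign. TMM already trims extreme genes, so this test could hardly show an effect of abundant genes that take up counts in the IgG libraries. With library totals in place of TMM, 2068 of the 2297 calls remained, so most calls did not depend on that trimming. A difference in depth does not account for the calls, since 95.5% of the 2297 remained after thinning. Binding by Exosc10 and other differences between the 2 antibodies stay open, because the only background measured was IgG.

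The libraries numbered 1 of both groups deviated from their group means together, with a correlation across genes of 0.34, and they were the shallowest of each group. The libraries numbered 3 did so as strongly, at 0.34, and those numbered 4 at 0.22. For the libraries numbered 1 lower depth is not the source, because the correlation was 0.37 after all libraries were thinned to the same total. A preparation or day shared by libraries of the same number may be, but it cannot be told apart from other differences: the labels record none, and although 8 of 8 libraries correlated best with their own number, the lowest same-number correlation, 0.095 for number 2, lay under the highest between different numbers, 0.123. No biological explanation was tested, as the labels give no difference between numbers. Without both of these libraries the count of calls was 5463.

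Among the 16716 tested genes, scarce genes were lower with Exosc10 relative to abundant genes. Genes below the count filter were not covered, and the trend was not run without the filter. The median log2 fold change was -0.24 in the bottom quintile by mean CPM and 0.09 in the top quintile. The difference was 0.33, and 0.33 to 0.34 under all 4 scalings, whereas the top quintile alone ran from 0.01 to 0.09. The size depends on the scale, as it was 0.23 on mean log2 CPM, a measure added after results had been seen, and 0.11, 0.14, 0.32 and 0.20 there for Exosc10 libraries 1 to 4 against the mean of the IgG libraries. Only 1 of the 35 splits, the real one, gave a difference as large in size, the highest other being 0.26, or 0.20 on mean log2 CPM. Depth and the libraries numbered 1 do not account for it, as the difference was 0.32 after thinning and 0.31 without those libraries. Binding by Exosc10 and a different background of the 2 antibodies stay open and were not tested, since input RNA was not analysed here.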
